A study of Ovis aries and Bos taurus with 6 samples.

How the data were processed

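Small RNA of extracellular vesicles (EVs) from milk was measured in 6 libraries, 3 from Ordos fine wool sheep and 3 from Holstein cows, all in mid lactation. Per the labels' protocols, EVs were isolated with a commercial exosome precipitation kit for body fluids, RNA was extracted with a column kit, and libraries were made with an Illumina TruSeq small RNA kit, which ligates an adapter to each RNA end before reverse transcription and PCR. A precipitation kit does not sort vesicles by the cell they came from, and adapter ligation and PCR favour some miRNAs over others, so shares of counts are not shares of molecules. The series' design text places the cow libraries in an earlier study of the same group, and no label gives a sequencing date or batch.

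The deposited counts are whole numbers of reads per miRNA row, 1 table per species and 1 column per library. Per the submitters' processing notes, cutadapt 1.14 and Bowtie were used, and the genome build, the miRBase release and the counting tool are not given in the sources used here. The sheep table has 685 rows, of which 84 carry a miRBase name, and lists a sequence for each row. The cow table has 779 rows, of which 276 carry a miRBase name, and gives no sequences. No library held the same values as another. The deposited TPM values equal the count divided by 1 constant per library and scaled up alike in all libraries, with no correction for length. That constant lies between 9859791 and 16091056 and is far above the miRNA counts of the library, and what it counts is not given in the sources used here.

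The miRNA counts came to 1110632, 2078695 and 1073914 in sheep replicates 1, 2 and 3, and to 328527, 556489 and 387723 in cow replicates 1, 2 and 3. A count of 0 allows up to 2.79 CPM in the sheep library of lowest depth and 9.13 in the cow library of lowest depth, from a floor of 3 counts. Wilson intervals (95%) of the shares given for single libraries were at most 0.168 percentage points to either side. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

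Rows were joined between species by mature name after the species prefix was removed, with the arm suffix kept. This gave 42 shared names, which hold 35.2% to 72.5% of the sheep counts and 7.45% to 17.1% of the cow counts. Counts of these miRNAs were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization factors, library size equal to the total of the shared miRNAs, default filterByExpr, which kept 38), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. The fixed lists of miRNA families and cell type markers, 21 in all, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 where at least 3 members were tested, with Benjamini-Hochberg adjustment over the lists. Shares of counts were compared with exact two-sided permutation tests, in which 3 libraries against 3 cannot give a p below 0.1. Correlations between species ran across miRNAs, which are not independent replicates, and carry no p.

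The lists and tests were fixed before the data were examined, as was the rule for the miRNAs named. It takes the 8 miRNAs with the largest log2 fold change in each direction among those past the threshold whose 3 sheep values all lie on one side of the 3 cow values, the 10 most abundant miRNAs of each species, and up to 4 tested members of highest mean CPM of each list described. Other miRNAs are said to have been chosen after their values were seen.

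A second join was added after the data were examined, because abundant sheep rows without a miRBase name listed the sequences of well known conserved miRNAs. Sheep rows were given a conserved name where at least 17 bases matched one of 91 textbook mature sequences with an offset of at most 2 bases and a difference in length of at most 4. This named 92 sheep rows under 79 names, which hold 90.6% of the sheep counts outside miRBase names. Where several sheep rows matched one name, their counts were summed. miRNAs joined by miRBase name kept a single sheep row, to which no row without such a name was added. Together with names that differ only in an arm suffix, 129 names were joined, 75 of them by sequence, and 120 passed the filter. Cow rows without a name could not be treated alike, as their sequences were not used here, so this join names more of the sheep counts (93.5% to 97.4%) than of the cow counts (14.2% to 27.2%).

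The alternatives were DESeq2 1.42.0, 3 other normalizations, totals of the whole table, other filters, joins and thresholds, limma on log2(TPM + 1) and log2(TPM + 10), estimated correlation and fry for the lists, the replicate number as a block, and each library left out in turn. Summing rows of one miRBase name changed nothing, as none occurred in more than 1 row of a table. The edgeR and camera steps were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, 50 times. With 38 miRNAs, edgeR called 1.52% of 2-fold, 36.9% of 4-fold and 76.5% of 8-fold changes and 0.22% of unchanged miRNAs. With the 120 miRNAs of the second join it called 1.81%, 16.6% and 49.7% of these sizes and 0.43% of unchanged miRNAs. camera called 2 of 198 simulated lists with shared names and 5 of 599 with the second join. The changed miRNAs were drawn at random and no list was shifted as a whole. The simulation therefore cannot show how often camera would find a shifted list. In the simulated counts most miRNAs were unchanged, changes went up or down at random, and none was above 8-fold. They held no shift in composition, while the TMM factors of the real libraries ran from 0.20 to 2.47. These rates therefore do not cover errors of normalization. R 4.3.3, Python 3.11.15 and SciPy 1.17.1 were used.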

Results

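Small RNA of milk EVs, membrane particles that cells shed and that carry miRNAs, was sequenced from 3 Ordos fine wool sheep and 3 Holstein cows to set the miRNA content of sheep milk EVs against that of cow milk EVs. The cow libraries belong to an earlier study, so species, breed and study cannot be told apart in any comparison here. The sheep libraries held 1110632, 2078695 and 1073914 miRNA counts and the cow libraries 328527, 556489 and 387723. These counts made up 10.5% ± 3.46 (SD, n = 3) of the constant behind the deposited TPM in sheep and 3.35% ± 0.977 in cow (exact permutation p = 0.1, the smallest that 3 against 3 allows). Rows with at least 10 counts numbered 347, 347 and 304 in the sheep libraries and 252, 261 and 258 in the cow libraries, from catalogues that differ. Thinned to the smallest total they were 274, 213 and 258 against 252, 230 and 246, so the groups overlapped at equal totals. The depth left for other rows still differed, as the largest row took 19.6% (sheep replicate 1) to 68.9% (cow replicate 3) of a library.

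In sheep milk EVs miR-148a, known as a major miRNA of lactating mammary epithelium, was the most abundant miRNA in every library. It took 19.6% (95% Wilson interval 19.5 to 19.7), 63.6% (63.5 to 63.7) and 38.0% (37.9 to 38.1) of the miRNA counts of replicates 1, 2 and 3. The mean was 40.4% ± 22.1 (SD, n = 3). In cow milk EVs miR-148a, miR-148b and miR-152 together took 0.178% ± 0.0642. There, 59.7% ± 8.92 of the counts fell in a single row with neither a miRBase name nor a sequence used here. The other abundant sheep miRNAs with a miRBase name were let-7b (4.66% ± 1.76), let-7a (3.47% ± 0.377) and miR-21 (2.68% ± 1.08), which is widely expressed. Further abundant sheep rows had no miRBase name but listed the sequences of miR-423-5p (7.56% ± 0.843), miR-151-3p (3.29% ± 1.31), the red blood cell miRNA miR-486 (2.62% ± 4.41), the liver miRNA miR-122 (2.59% ± 3.84), miR-100 (2.58% ± 0.711) and miR-375 (2.54% ± 2.20), known from endocrine and epithelial cells. Without sheep replicate 1 the means were 0.0723% for miR-486, 0.377% for miR-122 and 1.38% for miR-375. miR-92a, chosen after its values were seen, took 3.61% ± 1.98 summed over 2 sheep rows whose sequences differ by 1 base at the end. Among named cow miRNAs, miR-26a (4.04% ± 1.77), miR-191 (2.96% ± 1.90), miR-486 (1.51% ± 0.376), miR-151-5p (1.19% ± 0.639) and miR-423-5p (1.02% ± 0.272) were the most abundant, with miR-191 at 1.90% without cow replicate 2.

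**Figure D1:**
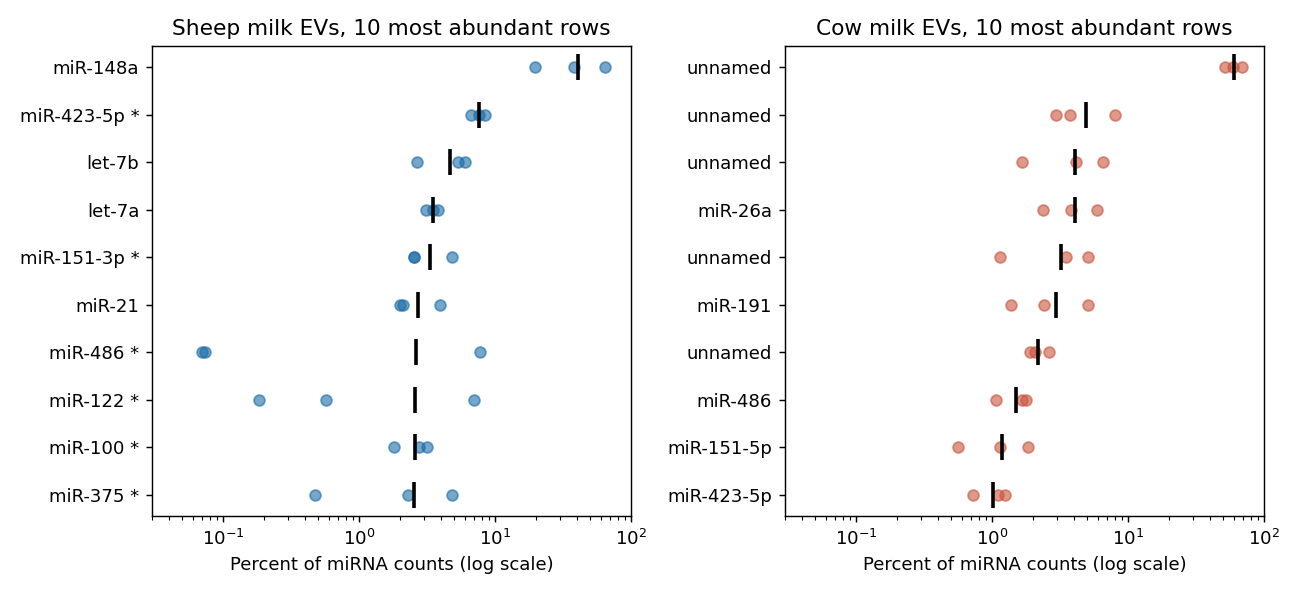
Percent of miRNA counts (x axis, log scale) in the 10 most abundant rows of each species; each point is 1 library and the black bar the mean of 3, and a star marks a sheep row without a miRBase name that was named by its sequence. miR-148a leads in sheep with a mean of 40.4%, an unnamed row leads in cow with a mean of 59.7%, and miR-486 and miR-122 lie far higher in 1 sheep library than in the others.

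The 10 most abundant rows together held 76.3% ± 10.6 of the sheep counts and 85.0% ± 2.28 of the cow counts (SD, n = 3), a difference that the exact permutation test did not separate from the spread between libraries (p = 0.3). Among shared miRNAs alone the order turned, with 95.8% ± 3.21 in sheep and 88.1% ± 2.20 in cow (exact permutation p = 0.1).

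Among miRNAs named in both tables, the epithelial miRNAs miR-200b and miR-200c, miR-148a, let-7b, let-7c and let-7i were higher in sheep, while miR-25, the lymphocyte miRNA miR-150, miR-30d, miR-22-3p and miR-191 were higher in cow. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, miR-148a was higher in sheep by 8.13 ± 1.30 on the log2 scale (SE, adjusted p = 1.77e-08), on 217525, 1322230 and 407936 sheep counts against 600, 1217 and 402 cow counts. miR-200c was higher by 6.05 ± 0.79 (adjusted p = 2.14e-11, edgeR). miR-200b had 2678, 1586 and 1525 counts in the sheep libraries and 0, 1 and 0 in the cow libraries, a ratio of normalized rates of 1434 with a 95% counting interval of 257 to 56639, or at least 224 without cow replicate 2. Of the 38 miRNAs tested, 20 passed an adjusted p of 0.05 in edgeR, 11 higher in sheep and 9 higher in cow. For 22 (57.9%) the sheep values did not overlap the cow values, where chance gives 10%.

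The remaining miRNAs that rule and threshold put higher in sheep were let-7c (4.90 ± 0.69), let-7i (4.20 ± 0.67), let-7b (2.95 ± 0.69), miR-127 of the imprinted DLK1-DIO3 region (2.66 ± 0.64) and miR-143, known from smooth muscle and stroma (1.57 ± 0.58), as log2 fold changes with SE. The largest differences in the other direction were miR-25 (-5.25 ± 0.80), miR-150 (-5.07 ± 0.65), miR-30d (-4.26 ± 0.63), miR-22-3p (-4.05 ± 0.62), miR-191 (-4.03 ± 0.69), let-7d (-2.95 ± 0.69), miR-374b (-2.86 ± 1.08) and miR-26a (-2.12 ± 0.67). Calls were lost for let-7b (1.13), miR-127 (1.21) and miR-143 (0.20) without normalization factors. With log2(TPM + 1) they were lost for let-7d (-1.49), miR-374b (-0.83) and miR-26a (-0.26), and with log2(TPM + 10) for miR-191 (-1.98). The replicate block ended the calls of miR-26a (-2.19) and miR-143. In the join by sequence below those of miR-127 (1.61) and miR-143 (0.48) ended. Leaving out 1 library ended the calls of miR-143 (1.54 without sheep replicate 2, 1.46 without cow replicate 1) and miR-374b (-2.58 without sheep replicate 1, -2.56 without sheep replicate 3, -1.86 without cow replicate 2). miR-143 was called in 13 of 21 other settings. Adjusted p values of these 13 miRNAs in edgeR ran from 2.14e-11 for miR-150 to 0.0194 for miR-374b. Members of the let-7, miR-30 and miR-148 families differ by few bases, so reads may have been split between them by the counting, and their single values are uncertain to that extent.

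Scaling moved the fold changes. The median change from the TMM values was -1.75 on the log2 scale without normalization factors, -0.36 with upper-quartile factors and 0.30 with totals of the whole table. The split into higher in sheep and higher in cow was 11 to 9 with TMM, 5 to 13 without factors and 7 to 10 with upper-quartile factors. limma on log2(TPM + 1), which also changes the test and the filter (42 miRNAs tested), gave a median change of 1.87 and a split of 20 to 5. In each of these, miR-148a, miR-200b, miR-200c, let-7c and let-7i stayed higher in sheep and past the threshold.

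**Figure D2:**
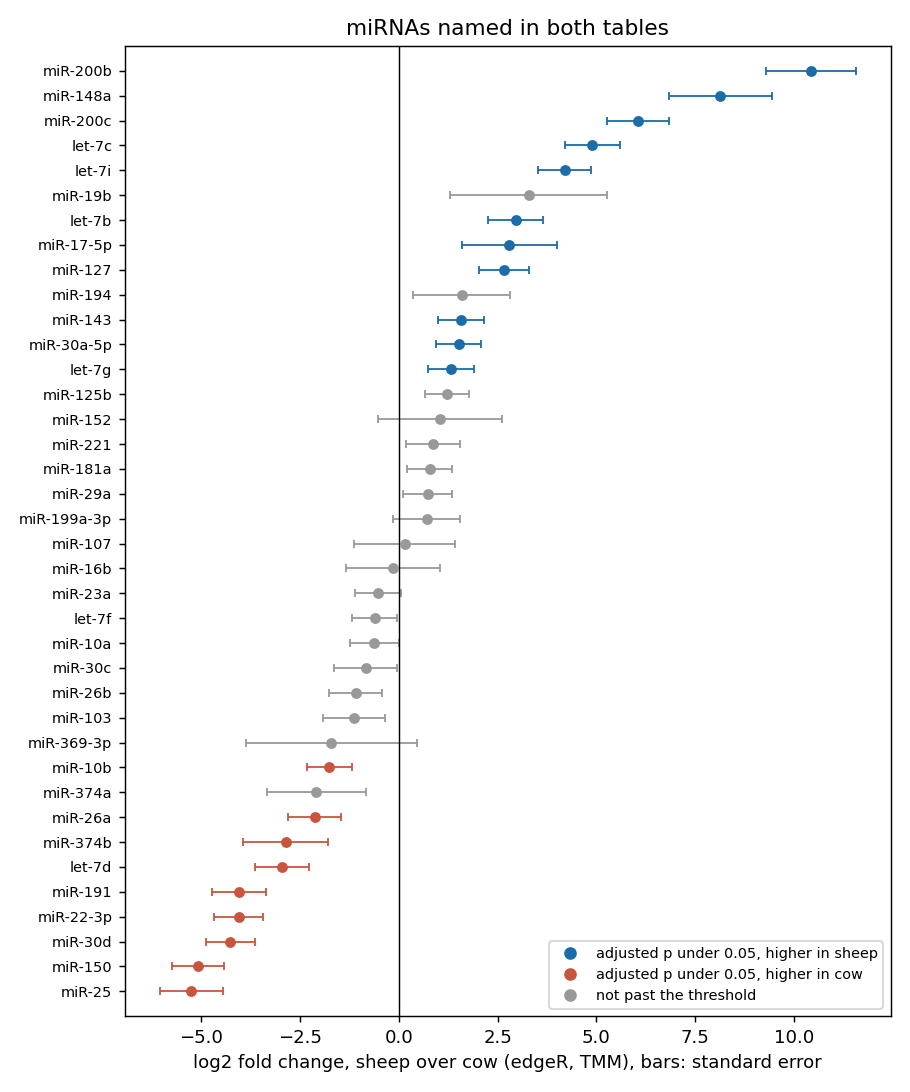
log2 fold change of sheep over cow (x axis) for the 38 tested miRNAs named in both tables, from edgeR with TMM; points are estimates, bars standard errors (n = 3 libraries per species), blue and red mark adjusted p under 0.05. miR-200b, miR-148a and miR-200c lie farthest to the sheep side and miR-25 and miR-150 farthest to the cow side; let-7g turned to -0.86 and miR-30a-5p to -0.19 without normalization factors, and miR-10b to 0.28 with log2(TPM + 1).

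In the fixed lists, let-7 was the family with most members tested. Of its 6 members 4 were higher in sheep (let-7b, let-7c, let-7i and, chosen after its values were seen, let-7g with 1.32 ± 0.58, but -0.86 without normalization factors and -0.063 in the join by sequence below), let-7d was higher in cow and let-7f did not pass (-0.61 ± 0.57), but passed as higher in cow without normalization factors (-2.64) and in the join by sequence (-1.9995). Adjusted over the list alone the counts were also 4 and 1. In the miR-30 family, miR-30a-5p was higher in sheep (1.51 ± 0.57, but -0.19 without normalization factors and 0.31, not past the threshold, in the join by sequence), miR-30d higher in cow, and miR-30c did not pass (-0.83 ± 0.80). In the family of miR-10, miR-99, miR-100 and miR-125, miR-10b was higher in cow (-1.75 ± 0.57, but 0.28 with log2(TPM + 1)), while miR-10a (-0.62 ± 0.62) and miR-125b (1.22 ± 0.56) did not pass over all miRNAs tested, and miR-125b passed adjusted over the list alone and in 11 of 21 other settings. In the miR-17-92 clusters, known for roles in cell proliferation, miR-17-5p was higher in sheep (2.80 ± 1.20, with overlapping libraries, but called in only 6 of 19 other settings, with 0.55 without normalization factors and 1.56 in the join by sequence), miR-25 higher in cow, and miR-19b did not pass (3.29 ± 1.99). Leaving out 1 library ended the calls of let-7g (0.87 and 1.24 without sheep replicates 2 and 3, 1.02 and 1.44 without cow replicates 1 and 3), miR-10b (-1.20 without cow replicate 1), miR-30a-5p (1.13 without sheep replicate 2) and miR-17-5p (1.77 without sheep replicate 3, 3.18, 2.68 and 3.55 without cow replicates 1, 2 and 3). The replicate block also ended the calls of let-7g, miR-10b, miR-30a-5p and miR-17-5p. The median (2.80) and mean (0.28) of the miR-17-92 list were above 0, while camera's direction was lower in sheep. None of these 4 lists passed camera, with adjusted p = 0.744 in each and 0.794 in each with an estimated correlation, and none had an unadjusted p under 0.05. fry, which asks whether the members move on balance one way, passed the miR-30 family (adjusted p = 0.0110).

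Lists with fewer than 3 tested members have counts only. Both tested miR-200 members and 1 of 2 in the miR-148 and miR-152 family were higher in sheep, 1 of 2 in the miR-26 family (miR-26a) was higher in cow, and miR-150, the leukocyte list's only tested member, was higher in cow. In the stromal list miR-143, and in the DLK1-DIO3 region miR-127, were higher in sheep, each 1 of 2. The single tested members of the miR-29, miR-23, miR-15, miR-181 and miR-221 lists did not pass, and the miR-183 cluster, red blood cell, endothelial, striated muscle, liver and neuronal lists had no tested member.

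As shares of all miRNA counts, the let-7 family took 13.2% ± 3.58 in sheep and 2.43% ± 0.694 in cow, the miR-200 family 0.372% ± 0.189 and 0.0152% ± 0.0160 (0.00605% without cow replicate 1), and the DLK1-DIO3 miRNAs 0.483% ± 0.286 and 0.0422% ± 0.0168 (SD, n = 3). Among shared miRNAs alone, where the largest cow row leaves the denominator, let-7 took 20.04% ± 9.84 and 15.3% ± 2.18 (exact permutation p = 0.4) and the DLK1-DIO3 miRNAs 0.631% ± 0.634 and 0.279% ± 0.162 (p = 0.5), and neither was separated; without sheep replicate 1 the DLK1-DIO3 miRNAs took 0.269% in sheep. The miR-26 family took 1.11% ± 0.334 in sheep and 4.12% ± 1.81 in cow. Of the constant behind the deposited TPM it took 0.111% ± 0.0324 and 0.147% ± 0.105, with overlap (exact permutation p = 0.9). The miR-17-92 clusters (0.0248% ± 0.0114 in sheep, 0.549% ± 0.0954 in cow) and the leukocyte list (0.0235% ± 0.0349 in sheep, 0.00336% without replicate 1, 0.637% ± 0.244 in cow) were lower in sheep by miRBase names, but turned to 3.80% ± 1.93 and 1.92% ± 0.604 in sheep once rows were named by sequence. Of the 15 lists with rows matched by miRBase name in both tables, 10 had shares that did not overlap, 5 higher in sheep and 5 higher in cow, where chance gives 10%. That even split depends on the naming and on the denominator. With sheep rows also named by sequence, which no cow row could be, 14 of 21 lists did not overlap, 12 of them higher in sheep. Among shared miRNAs alone 10 did not overlap, 8 of them higher in cow. As shares of the constant behind the deposited TPM, the miR-10, miR-15 and miR-26 families overlapped. The miR-29, miR-181 and miR-221 lists then lay higher in sheep without overlap. Of the 15 lists only the miR-17-92 clusters and the leukocyte list stayed higher in cow without overlap. No list passed the exact permutation tests, whose smallest p is 0.1.

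With the join by sequence, added after the data were examined, 120 miRNAs were tested and miR-375, miR-7 and the muscle miRNA miR-1 were among those farthest to the sheep side. edgeR put miR-375 higher in sheep by 6.49 ± 0.85 on the log2 scale (adjusted p = 2.36e-05). miR-7 passed (adjusted p = 3.62e-05) on 0, 6 and 0 cow counts, a ratio of 258 with a counting interval of 119 to 704, or 150 without sheep replicate 3 and at least 271 without cow replicate 2. 3 miRNAs past the threshold had no count in any cow library, so only a lower bound is given. Against a floor of 3 counts over the cow group, miR-196b was at least 44.8-fold, miR-210 at least 12.1-fold and miR-34a at least 12.0-fold higher in sheep. These bounds cover counting in the named cow rows only, since cow reads of these miRNAs may lie in cow rows without a name. The same limit holds for the ratios of miR-7, miR-1 and miR-200b. It also holds for every other miRNA called higher in sheep in either join. Rows with a miRBase name held only 15.8% to 29.0% of the counts of a cow library. Sheep replicate 3 held most counts of miR-196b and miR-210, and without it these bounds were 20.1 and 6.59. Without cow replicate 2, which lowers the cow depth, the 3 bounds were 23.5, 6.32 and 6.26. miR-1 had 2 cow counts and a ratio of 1655 with a counting interval of 458 to 13667. Of its sheep counts, 28528 came from replicate 1 against 1052 and 698 in the others, and without it the ratio was 148.5. Without sheep replicate 2 it was 2721, and without cow replicate 2 it was 867. Higher in cow were miR-151-5p (-8.57 ± 1.18), miR-30b-5p (-8.34 ± 1.00) and miR-335 (-5.49 ± 1.37, but -1.12 and not past the threshold with log2(TPM + 1)), beside miR-25, miR-150, miR-30d and miR-191. With 1 library left out, miR-151-5p ran from -11.07 (without sheep replicate 3) to -7.61 (without sheep replicate 1). miR-30b-5p ran from -9.33 (without sheep replicate 2) to -6.88 (without sheep replicate 1). miR-362-5p was also higher in cow, with 2 sheep and 33 cow counts, 23 of these in cow replicate 1. It was at -0.73 and not past the threshold with log2(TPM + 1), and was not tested without cow replicate 1. In this join 66 miRNAs passed, 38 higher in sheep and 28 higher in cow, or 20 and 33 without normalization factors and 72 and 8 with limma on log2(TPM + 1), again with another test and filter. Of the 20 calls above, 15 were called again with the same sign. The join shifted the fold changes of the shared names by a median of -1.22.

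All 3 tested miR-200 members (miR-200b, miR-200c and miR-141 with 4.19 ± 1.08) and 2 of 3 in the miR-148 and miR-152 family (miR-148a and miR-148b with 3.73 ± 0.77) were higher in sheep in this join. Of 8 leukocyte miRNAs 4 were higher in sheep, among them miR-146a (4.49 ± 0.70) and miR-155 (2.53 ± 0.81, not past the threshold with 2.19 without cow replicate 3 and 2.05 without normalization factors), and 3 higher in cow, among them miR-342 (-4.90 ± 0.73, but -1.82 and not past the threshold with log2(TPM + 1)). In the family of miR-10, miR-99, miR-100 and miR-125, miR-100 was higher in sheep (3.27 ± 0.56), and miR-99a-5p (-4.15), miR-10b (-2.94) and miR-125a (-1.71) were higher in cow, which became -1.05, 0.28 and 1.18 with log2(TPM + 1), none past the threshold. The call of miR-125a also ended without sheep replicate 2 (-1.33), sheep replicate 3 (-1.45), cow replicate 1 (-1.38) and cow replicate 3 (-1.69). None of the 12 lists passed camera (lowest adjusted p = 0.186, for the miR-200 family, and 0.898 with an estimated correlation); 2 had an unadjusted p under 0.05, and fry passed 3 lists. The values of the blood, liver and muscle lists moved with 1 sheep library, as given next.

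Sheep replicate 1 stood apart in miRNAs of blood, liver and muscle, and in others too. miR-486 took 7.72% (95% Wilson interval 7.67 to 7.77) of its counts against 0.0741% and 0.0705% in sheep replicates 2 and 3. miR-122 took 7.02% (6.97 to 7.07) against 0.184% and 0.570%, and miR-1 took 2.57% (2.54 to 2.60) against 0.0506% and 0.0650%. The lymphocyte miRNA miR-150 and the endothelial miRNA miR-126-3p were also higher there (chosen after their values were seen), at 0.0637% and 0.439% against at most 0.00363% and 0.123% in the others. miR-146a was lowest there, at 0.949%. Outside these lists (chosen after their values were seen), the epithelial miRNA miR-429 had 261 counts there against 0 and 2, and miR-215 had 4595 against 212 and 318, while miR-34b had 8 against 1292 and 1998 and miR-31 had 16 against 649 and 1345. Without this library edgeR called 20 miRNAs among shared names, 19 of them also called with all libraries. In the join by sequence it called 67, of which 53 were among the 66 called with all libraries. There miR-486 moved from -1.14 ± 1.09 (adjusted p = 0.366, edgeR) to -4.80 ± 0.65, higher in cow (adjusted p = 9.3e-12). miR-122 fell from 3.43 to 1.80 and stayed past the threshold.

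**Figure D3:**
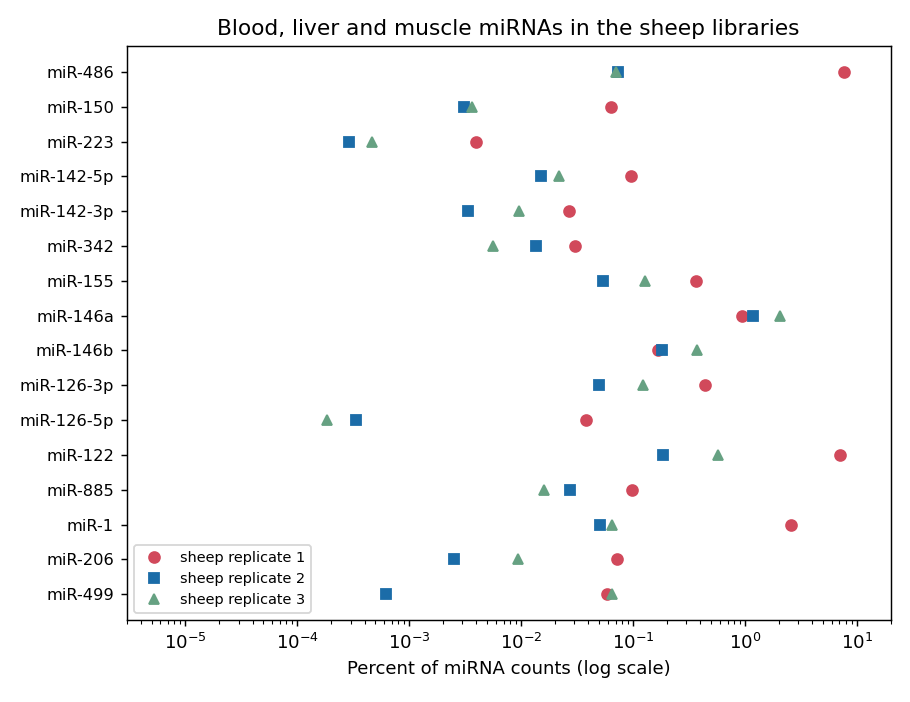
Percent of miRNA counts (x axis, log scale) of blood, endothelial, liver and striated muscle miRNAs in the 3 sheep libraries, 1 point per library, miRNAs chosen from the fixed lists. Replicate 1 is highest for most of them, with 7.72% of counts in miR-486, but not for miR-146a, miR-146b and miR-499.

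The order of abundance was shared in part. Across the 42 shared miRNAs, mean log2(CPM + 1) correlated between species with Spearman's rho of 0.611 and Pearson's r of 0.614. Libraries of one species correlated with each other at rho of 0.933 to 0.941 in sheep and 0.925 to 0.952 in cow. Among the 20 most abundant rows of each species, let-7b, let-7f and miR-26a occurred in both, and among the 10 most abundant none did by miRBase name. With sheep rows named by sequence and arms ignored, let-7a, miR-423, miR-486, miR-92a and miR-151 joined them, the last with different arms, which makes 8 of 20. miR-423-5p and miR-486 were then among the 10 most abundant of both species, but miR-486 ranked 67 in sheep without replicate 1.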

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

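The tests in this part were chosen after the results were seen; the scalings and left-out libraries they draw on were listed before the data were examined, except the join by sequence.

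A large part of the counts lies outside the comparison of shared names. Rows without a miRBase name held a mean of 38.9% of the sheep counts and 77.9% of the cow counts, and the largest of these cow rows alone held 59.7%, all far above what a count of 0 allows. In sheep 90.6% of these counts were named by sequence, and in cow none were.

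miR-148a dominated sheep milk EVs and was scarce under its own name in cow milk EVs. The values argue against the choice of scaling as the whole cause: the lowest log2 fold change over the scalings was 5.63 ± 0.47 (SE, without normalization factors), and each passed the threshold. A single library does not account for it either, as the lowest value with 1 library left out was 6.99 ± 0.96 among shared names and 5.93 ± 0.67 in the join by sequence (both without sheep replicate 2), and each left-out fit passed the threshold. Whether cow miR-148a reads were counted in the largest unnamed cow row cannot be told apart from a true scarcity: with all counts of that row added to miR-148a, the log2 ratio of mean shares would be -0.57, and no sequence of that row was used here. A difference between sheep and cow, or between the 2 studies, stays open and untested.

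Sheep replicate 1 held far more miR-486, miR-122 and miR-1 than the other sheep libraries. Its lower share of miR-148a leaves 1.63-fold more room for other miRNAs, against a lowest fold of 18.6 among the 3, which argues against that as the cause. RNA of blood may have entered this library. In the log2 ratio of this library to the other sheep libraries, 8 of 10 other detected blood and endothelial miRNAs lay above the median of 140 other known rows. The median of all 10 was 1.65 above that of the 140 (one-sided permutation p = 0.00015). With 1 value per hairpin 6 of 8 lay above, and the median of all 8 was 1.51 higher (permutation p = 0.0008). The 10 are members of the leukocyte and endothelial lists, with no red blood cell miRNA among them. These p values permute miRNAs, which vary together, and do not cover variation between libraries. Rows outside the lists moved as far, up (miR-429) or down (miR-34b), and miR-146a and miR-146b, which many cell types express, were lower there and no sheep row matched the miR-451 sequence. For liver and striated muscle RNA too few other list members were matched to decide: miR-885 alone lay 1.64 higher (permutation p = 0.0773), and miR-206 and miR-499 had a median 1.67 higher (permutation p = 0.0556). The striated muscle list spells miR-133 otherwise, so the sheep row miR-133 was counted among the other known rows. It lay above their median, between miR-499 and miR-206. No test was run with miR-133 as a muscle member, so striated muscle RNA stays undecided. Variation between animals stays open and untested.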

How the results depend on the processing

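The join by sequence, its settings and the fit without miR-148a were added after the data were examined. The count of called miRNAs among shared names was 20 with TMM and edgeR and stayed within 1.5 times of that in each alternative set beforehand, from 14 with the replicate block to 25 with limma on log2(TPM + 1); it rose to 66 with the join by sequence, where more miRNAs were tested (38 higher in sheep, 28 higher in cow). The number higher in sheep, 11, fell to 5 without normalization factors and to 7 with upper-quartile factors, with glmTreat against a 2-fold change, at an adjusted p of 0.01 and with the replicate block, and rose to 20 with log2(TPM + 1). The number higher in cow, 9, fell to 5 with log2(TPM + 1), also at a mean TPM of at least 10, and to 4 with log2(TPM + 10). With 1 library left out, 17 to 23 miRNAs were called. In the join by sequence 38 higher in sheep became 20 without normalization factors and 72 with log2(TPM + 1), and 28 higher in cow became 8 with log2(TPM + 1). The cause was not tested, beyond the shifts of all fold changes with scaling given in the results.

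Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0904, 0.208 and 0.107, and sheep replicate 1 and sheep replicate 3 correlated best with another number. With the replicate block 14 miRNAs were called, 7 in each direction, and no list.

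No list passed camera in any alternative, while fry passed 1 list among shared names and 3 in the join by sequence; fry asks another question. The real split of the 6 libraries gave 20 calls, 66 in the join by sequence and 0 lists, and the highest of the other splits gave 0 in each case. The 10 splits are too few for a share under 0.05: 1 split of 10 reached the real number of calls, in both joins, and 10 of 10 reached the 0 lists.

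Of the 25 named miRNAs among shared names, 20 were called. Their 413 values under other settings kept sign and call in 350 cases, lost the call in 57 and turned sign in 6. let-7c, let-7i, miR-148a, miR-150, miR-200b, miR-200c, miR-22-3p, miR-25 and miR-30d were called in every setting that tested them. miR-17-5p was called in 6 of 19, let-7g in 9 of 21 and miR-143 in 13 of 21. The 5 not called gave 100 values, of which 15 passed (11 of miR-125b, 2 of let-7f and 2 of miR-19b) and 14 turned sign. With log2(TPM + 1), with or without a minimum mean, let-7f turned to 1.12, miR-10a to 1.33, miR-10b to 0.28 and miR-30c to 1.13; with log2(TPM + 10) they turned to 1.09, 1.13, 0.26 and 0.71. With totals of the whole table miR-10a turned to 0.065, and without normalization factors let-7g turned to -0.86, miR-125b to -0.51 and miR-30a-5p to -0.19. In the join by sequence let-7g turned to -0.063. With 1 library left out let-7f ran from -1.05 to 0.085, miR-10a from -0.86 to 0.090 and miR-30c from -1.25 to 0.26, each turning only without cow replicate 2. The cause was not tested.

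The difference in the share of the 10 most abundant rows turned from -8.74 to 7.72 percentage points among shared miRNAs only, where the denominator leaves out the largest cow row. Lists with shares that did not overlap numbered 16 of 21, but 6 of these had no sheep row matched by miRBase name, so their separation was fixed by the naming. The named sheep rows miR-133 and miR-218a were not matched to the striated muscle and neuronal lists, which spell these names otherwise. Their shares overlapped the cow shares of those lists (0.0123%, 0.00125% and 0.0104% for miR-133, 0.0484%, 0.0136% and 0.0277% for miR-218a). Lists that did not overlap numbered 10 with shared miRNAs only, and 14 with sheep rows named by sequence, 12 of them higher in sheep. Spearman's rho between species was 0.523 for miRNAs past the filter and 0.564 in the join by sequence. Of 10, 20 and 50 most abundant rows, 0, 3 and 8 names were shared, and 8 of 20 with sheep rows named by sequence and arms ignored, where miR-151 counts although its arms differ. Rows detected averaged 333 in sheep and 257 in cow at 10 counts, 510 and 408.7 at 1 count, and 39.3 and 33.7 among shared names. Thinned to the smallest total they were 248 and 243, so most of that gap goes with depth. In the simulated counts few 2-fold changes were called.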

Other observations

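Arms of the same hairpin had different shares in the matched rows of the 2 species' tables, a pattern chosen after its values were seen. Of the miR-151 counts, the 5p arm took 0.183% ± 0.211 in sheep (0.0627% without replicate 3) and 95.7% ± 0.764 in cow (SD, n = 3, exact permutation p = 0.1, the smallest possible). The sheep libraries held 25, 19 and 220 counts of miR-151-5p beside 27886, 52900 and 51594 of miR-151-3p, and the cow libraries 3774, 10251 and 2197 beside 177, 542 and 80. The 5p arm of miR-126 took 2.95% ± 4.40 in sheep (8.02% in replicate 1, and a mean of 0.411% without it) and 43.5% ± 1.84 in cow (exact permutation p = 0.1), and that of miR-142 took 76.4% ± 6.31 and 99.7% ± 0.502 (exact permutation p = 0.1). The cow shares of miR-142 rest on few counts, 12, 170 and 114 of the 5p arm and 0, 0 and 1 of the 3p arm. The 5p arm of miR-423 was alike, at 89.7% ± 2.24 in sheep and 86.3% ± 3.15 in cow (exact permutation p = 0.2). The sheep arms of these 4 hairpins were named by sequence, and no explanation was tested. The cow arms come from rows with a miRBase name only. Cow reads of either arm may lie in rows without a name, which held 71.0% to 84.2% of the counts of a cow library. A difference in arm use therefore cannot be told apart from one in naming.

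A hypothesis formed after the fold changes were seen was that sheep rows listing a shortened sequence lost reads, as let-7d, miR-30d and miR-25 were low in sheep and the first 2 list short sequences. Across the 38 tested miRNAs the listed sheep length and the log2 fold change gave Spearman's rho of 0.326 (one-sided permutation p = 0.0228) and Pearson's r of 0.294, but without these 3 rho was 0.194 over 35 miRNAs (permutation p = 0.133). Shortened sequences may contribute, but the relation rests on the miRNAs that prompted it, so it stays undecided, and miRNAs are not independent replicates.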
